A study of Parhyale hawaiensis with 10 samples.

How the data were processed

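ATAC-seq, which cuts accessible DNA with the Tn5 transposase, had been applied to 10 libraries from the crustacean Parhyale hawaiensis. The labels give 3 whole embryos (single embryos at stages 20, 23 and 24), 3 libraries of embryonic legs from pools of embryos at stages 25 to 26, 3 libraries of adult legs and 1 library in which naked DNA of a whole adult was tagmented in place of nuclei. Embryonic legs were the T4 to T8 legs and adult legs the T4 and T5 legs, per the labels, so that age and leg identity differ together. Whole embryos and embryonic legs were also lysed in different ways, per the labels' protocols.

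Bowtie2 2.5.4, SAMtools 1.21, bedtools 2.31.1, Picard and MACS2 2.2.7.1 are named per the submitters' processing notes, which give neither their roles nor their order. The genome build name, the control library, the calling threshold, the genome size and any shift of reads for the transposase are not given in the sources used here; scaffold names begin with phaw_50. Peaks had been called in each library separately, since each library has its own deposited peak list. The deposited fold enrichment of a peak is a ratio, which the values show to be the summit pileup plus 1 divided by the expected pileup plus 1. The deposited p-value and q-value columns hold −log10 values, and the lowest −log10 q was 1.3 in every list, which is a q-value of 0.05. The deposited score column, a display score, was not used for any result. The folds and q-values are the authors' values of single peaks and were used to describe, rank or filter peaks within a list. Depth is divided out of the folds only in part, so where folds of several lists are averaged or given side by side they describe those lists and are not on a common scale.

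Depth is not stated in the lists and was recovered from them. Fold and p-value together gave a whole-number pileup for 99.98% to 100% of the rows of a library. A row counted as solved when the −log10 p of that pileup lay within 0.002 of the deposited value, with a wider tolerance for large values. The most frequent expected pileup, which recurs in 18.8% to 39.5% of rows, was taken as the genome-wide background and serves as a measure of relative depth. It was 0.404, 0.233 and 0.555 for the embryos at stages 20, 23 and 24, 0.457, 0.394 and 0.526 for embryonic legs 1 to 3, 0.482, 0.451 and 0.252 for adult legs 1 to 3, and 5.11 for naked DNA. The narrowest peak was 122 to 152 bp wide in the other nuclei libraries, 278 bp in naked DNA and exactly 200 bp in the stage 24 embryo, whose expected pileups also rise in steps set by 200 bp. A fixed length of 200 bp in peak calling would give these values; the setting is not given in the sources used here, and the stage 24 pileup may not be on the scale of the others. The lists hold no read totals, and intervals on shares of regions cover counting error only.

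Rows with the same start and end, which are several summits of 1 peak, were counted as 1 peak. Regions were the merged union of the peaks of the 9 nuclei libraries, and a region was present in a library that had a peak overlapping it by at least 1 bp. Embryonic-leg-only regions were present in all 3 embryonic leg libraries and in no adult leg library, adult-leg-only regions the reverse, and leg-wide regions were present in all 6. Similarity of 2 libraries was the Jaccard index, the shared base pairs divided by the base pairs covered by either. Overlap by chance was measured with 100 circular shifts of peaks within the 158 scaffolds on which peaks reach at least 1 Mb. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlaps were checked against bedtools 2.31.1. On simulated lists with 87308 peaks, all 200 seeded restricted regions of the comparison of embryonic with adult legs were recovered, and 2909 of 2909 simulated pileups were solved. The simulated lists held every other peak in all 6 leg libraries. Their recovery therefore checked the handling of intervals and not the detection of restricted regions in real libraries.

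The samples, the region classes, the tests of the comparisons and most alternatives were fixed before the data were examined; tests and alternatives chosen later are named as such where they are given. Library values were compared with exact two-sided permutation tests, similarity with exact one-sided permutations of the library labels, and region classes with Fisher's exact test, two-sided, and odds ratios with 95% intervals. Regions are not independent replicates, and such intervals describe these libraries. Shares carry 95% Wilson intervals. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of lists held the same peaks. Alternatives were a q-value of at most 1e-05, the strongest 48324 peaks of every nuclei library (the size of the shortest list), an overlap of at least 50% of the shorter interval, removal of peaks that overlap naked DNA, windows of 250 bp on each side of the summits, each replicate left out in turn and the replicate number as a block.

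The regions named were to be the 12 embryonic-leg-only and 12 adult-leg-only regions, and the 6 regions of all 9 nuclei libraries, with the highest mean percentile of fold within each library and no overlap with naked DNA, and the 3 windows of 100 kb with the most regions of each restricted class. The first 3 of each set are given by position and the others are summarised. Position relative to genes, gene lists, sequence motifs and base composition had been planned, but a genome and annotation were not used here, so these were not run and no region is assigned to a gene.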

Results

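Chromatin accessibility was profiled in whole embryos, in developing legs and in adult legs of Parhyale hawaiensis, an amphipod crustacean with a large genome, to locate candidate regulatory sequence. The 3 whole embryos were single animals at stages 20, 23 and 24 and have no replicates. Embryonic legs (stages 25 to 26) and adult legs had 3 libraries each, and 1 library of naked DNA measured where the transposase cuts without chromatin. Merging the peaks of the 9 nuclei libraries gave 280946 regions on 28600 scaffolds carrying a peak in any library. Of these, 153621 (54.7%) were called in 1 library and 8294 in all 9.

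The first comparison asked whether embryonic and adult legs differ in how much of the genome was called accessible. Embryonic legs gave 94717 ± 22021 peaks and adult legs 58031 ± 15804 (SD, n = 3 each), a ratio of 1.63. Every embryonic leg library (87308, 77357 and 119487 peaks) lay above every adult leg library (76268, 49502 and 48324 peaks), although embryonic leg 2 exceeded adult leg 1 by little. The peaks covered 27.2 ± 5.98 Mb in embryonic and 17.9 ± 5.58 Mb in adult legs. The embryos at stages 20, 23 and 24 had 60435, 56606 and 119994 peaks. The exact two-sided permutation test gave p = 0.1 for the number of peaks, the smallest p that 3 libraries against 3 allow, and p = 0.2 for the covered length (n = 3 each). Background pileup, the measure of depth, was 0.459 ± 0.0657 in embryonic and 0.395 ± 0.124 in adult legs (exact p = 0.6, n = 3 each, two-sided), and the adult library with the fewest peaks was the shallowest of the 6 at 0.252. Divided by fragment length, it was 3.61 ± 0.508 fragments per kb in embryonic and 2.79 ± 0.904 in adult legs (exact two-sided p = 0.3, n = 3 each), a ratio of 1.29.

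Naked DNA served as the background of the assay. It gave 161533 peaks with a median fold of 2.70, against 4.34 to 6.34 in the nuclei libraries. These folds are not on a common scale and do not show weaker enrichment. The background pileup was 5.11 in naked DNA and 0.233 to 0.555 in the nuclei libraries. Of the peaks of embryonic legs, 18.4% ± 1.24 overlapped a naked DNA peak, and of those of adult legs 26.4% ± 5.35 (SD, n = 3 each). The difference of −7.92 percentage points was larger than either spread, with an exact two-sided permutation p of 0.1, the smallest possible (n = 3 each). The share was 30.1%, 26.2% and 15.6% in the embryos at stages 20, 23 and 24. On scaffolds of at least 1 Mb it was 13.7% to 24.8%, against 4.73% to 4.93% after circular shifts on the same scaffolds, so every nuclei library overlapped naked DNA more often than random placement did. Among the tenth of peaks with the highest fold, the share reached 59.1% at stage 20 and 41.1% at stage 23, against 18.99% at stage 24, 20.4% ± 1.07 in embryonic legs and 29.5% ± 4.84 in adult legs (SD, n = 3 each). Among the tenth with the lowest fold it was 17.6% ± 1.65 in embryonic and 18.6% ± 1.08 in adult legs (exact two-sided permutation p = 0.5, n = 3 each).

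**Figure D1:**
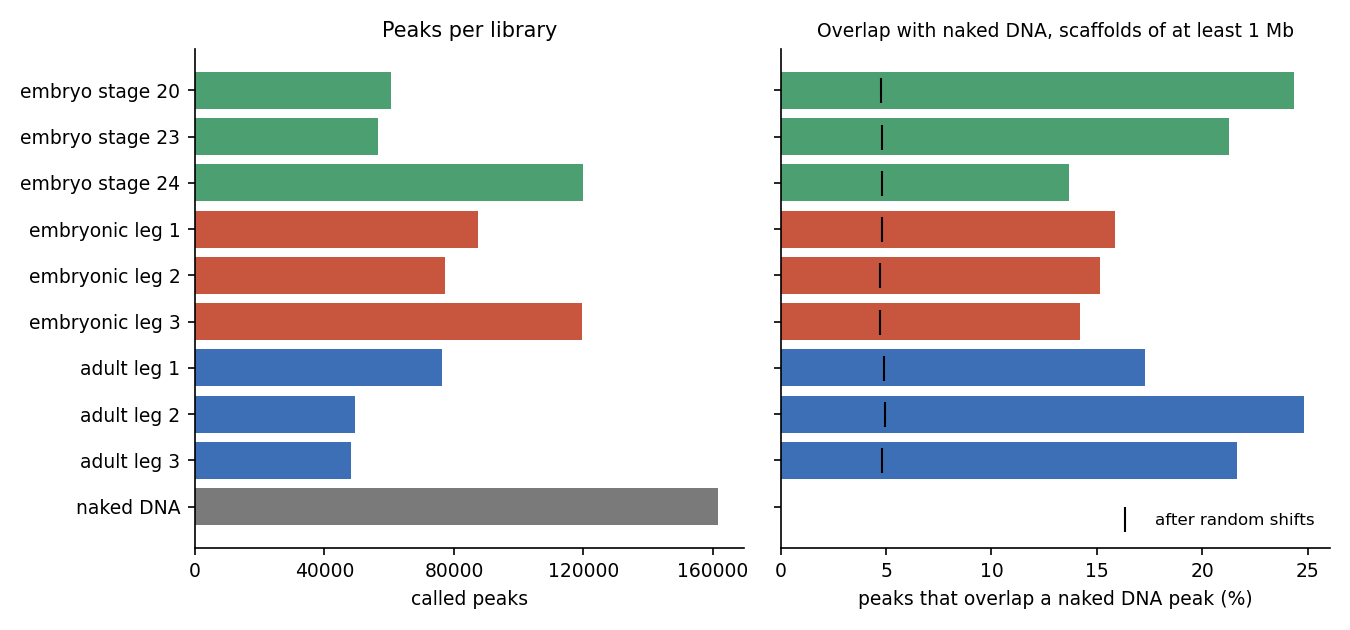
Left, the number of called peaks (horizontal axis) in each of the 10 libraries; right, the percent of each nuclei library's peaks on scaffolds of at least 1 Mb that overlap a naked DNA peak, with a vertical mark at the mean after 100 random shifts. Embryonic legs lie at 77357 peaks or more and adult legs at 76268 or fewer, and every bar on the right (13.7% to 24.8%) lies above its mark of 4.73% to 4.93%.

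Libraries of one tissue were next compared with libraries of other tissues. Embryonic leg libraries shared the most sequence, with a mean Jaccard index of 0.418 (0.409 to 0.436 over 3 pairs), and adult leg libraries followed at 0.319 (0.302 to 0.333). Embryonic with adult legs gave 0.267 over 9 pairs (0.208 to 0.343), and the 3 embryo stages shared 0.176 on average. Adult leg 1 stood closer to embryonic legs (0.302 to 0.343) than the other adult libraries did (0.208 to 0.266), and its index with them reached that with its own group (0.302 and 0.322). With the same number of peaks in every library it shared 0.369 to 0.387 with embryonic legs and 0.335 and 0.371 with the other adult legs. Each nuclei library overlapped naked DNA by a Jaccard index of only 0.0362 to 0.0541. Similarity within tissues exceeded similarity between tissues by 0.0786, and none of the other partitions of the 9 libraries into 3 sets of 3 reached it (exact permutation p = 0.00357, one-sided, the smallest that 280 partitions allow). The embryos did not share in this difference: the mean index was 0.176 among them, but at stages 20, 23 and 24 it was 0.197, 0.207 and 0.265 with embryonic and 0.188, 0.207 and 0.165 with adult legs. Without the stage 24 embryo, a setting chosen after seeing the data, the difference was 0.116. Within the legs alone the difference was 0.101, the largest of the 10 splits (exact permutation p = 0.1, one-sided, the smallest possible). Without embryonic leg 1 or embryonic leg 3 the difference over the nuclei libraries fell to 0.0507 and 0.0503 with p of 0.025 and 0.0286 by the exact permutation test, and without adult leg 1 the difference between legs rose to 0.156. The difference between legs fell to 0.0749 without embryonic leg 1 and to 0.0686 without embryonic leg 3, each with an exact one-sided permutation p of 0.2.

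**Figure D2:**
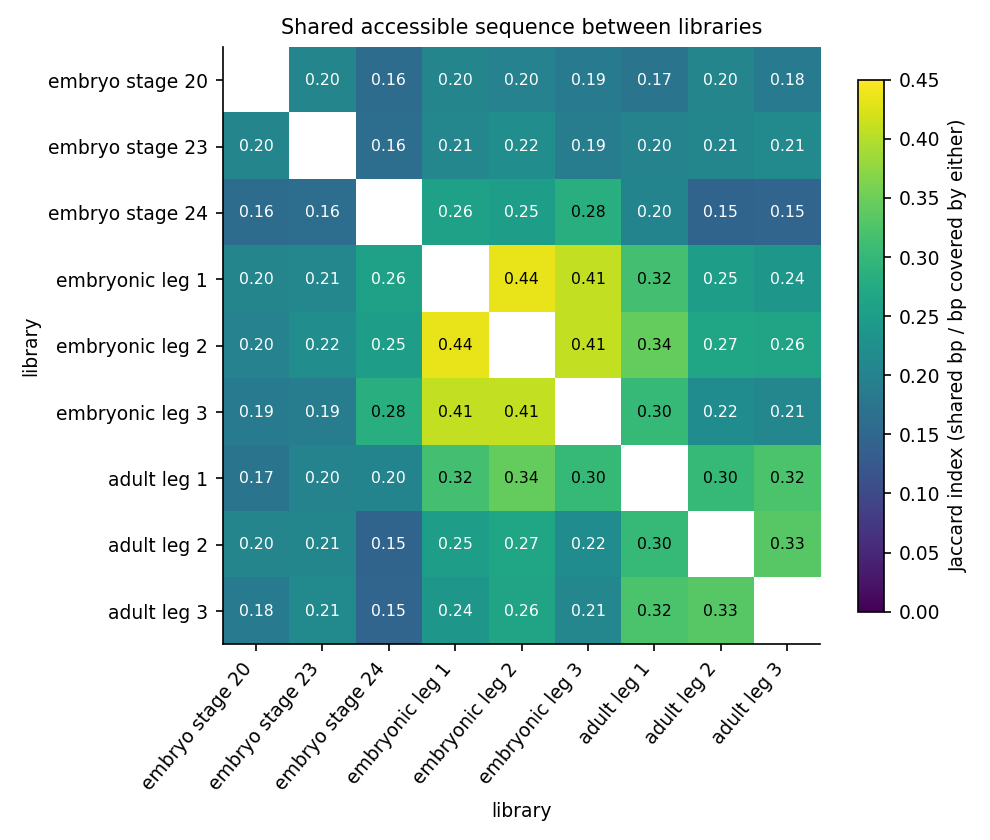
Jaccard index (shared base pairs divided by base pairs covered by either library) for each pair of the 9 nuclei libraries, with libraries on both axes and the index as colour and number. Embryonic legs form the brightest block (0.409 to 0.436), and stage 24 is the embryo closest to them.

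Regions restricted to one leg type were counted to find sequence accessible at one age of the leg. Embryonic legs held 12371 regions that were called in all 3 of their libraries and in no adult leg library, and adult legs held 1703 of the reverse kind, a ratio of 7.26. A further 17221 regions were called in all 6 leg libraries. Thus 25.2% of the 49079 regions found in all 3 embryonic leg libraries were absent from adult legs, and 7.61% of the 22385 regions found in all 3 adult leg libraries were absent from embryonic legs. Leg-wide regions were stronger (median of the mean fold 11.2) than embryonic-leg-only (6.61) or adult-leg-only regions (6.54). The class rule favours this order, because a restricted region had to be missed in 3 libraries and weak regions are missed more readily. Of the leg-wide regions 33.1% (95% Wilson interval 32.4% to 33.8%) overlapped a naked DNA peak, of the adult-leg-only regions 22.5% (20.6% to 24.6%) and of the embryonic-leg-only regions 10.2% (9.64% to 10.7%). With the same 48324 peaks taken from every library the counts were 7022 and 2872, a ratio of 2.44. An exact test of presence in a single region could give no two-sided p under 0.1 with 3 libraries against 3, so none was run per region. The ratio was 3.77 without adult leg 2 and 4.06 without adult leg 3, the adult-leg-only count was 2558, 3631 and 3247 without adult leg 1, 2 and 3, and the embryonic-leg-only count was 20444 without embryonic leg 2 and 21381 without adult leg 1.

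The restricted share depended on peak strength in both leg types. Of regions in all 3 embryonic leg libraries with a mean fold under 5, 50.5% (95% Wilson interval 49.0% to 51.9%) were absent from adult legs, and this share fell to 2.15% (1.72% to 2.67%) at a fold of 20 or more, 77 of 3589 regions. The reverse share fell from 17.3% (15.7% to 19.1%) to 0 of 745 regions, with an upper Wilson bound of 0.513%. The other usual limit for a count of 0, 3 counts of the 745, is 0.403%. The folds of the 2 leg types are not on the same scale, since the leg-wide regions had a median fold of 12.6 in embryonic and 9.74 in adult legs, so the shares are not compared between leg types at a given fold.

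**Figure D3:**
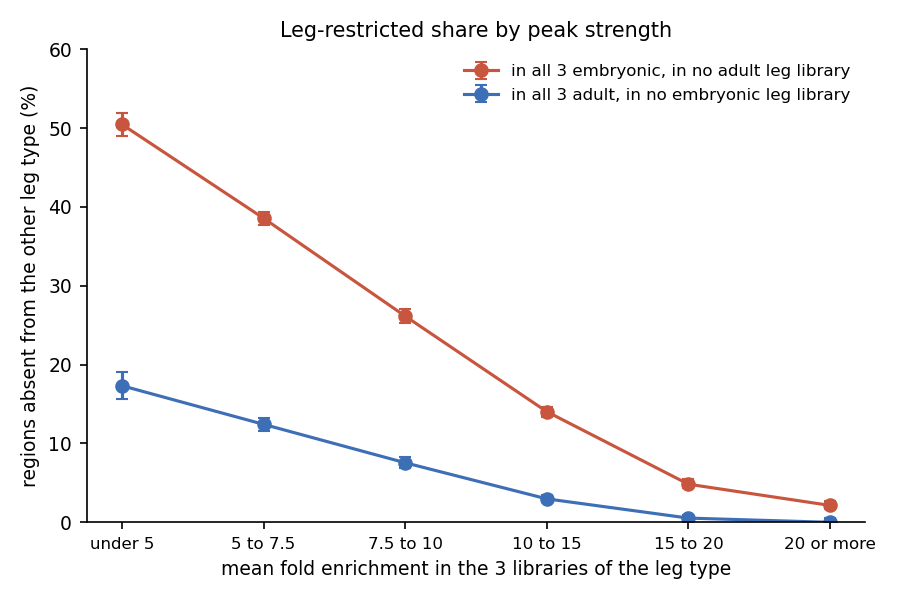
Percent of the regions called in all 3 libraries of a leg type that no library of the other type holds (vertical axis), by mean fold enrichment in their own 3 libraries (horizontal axis), with 95% Wilson intervals as bars. Embryonic legs fall from 50.5% to 2.15% and adult legs from 17.3% to 0; the folds of the 2 leg types are not on the same scale.

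The strongest restricted regions were named by the rule fixed beforehand. The 12 embryonic-leg-only regions had mean folds of 25.4 to 38.5, led by scaffold phaw_50.185447 at 15 to 300 (fold 38.5 ± 2.50), phaw_50.111174 at 20 to 356 (30.7 ± 1.79) and phaw_50.283811 at 34436253 to 34436502 (30.4 ± 3.85; SD, n = 3 each). Of these 12, 11 were also called in a whole embryo, all 11 of them at stage 24, and 7 lay on scaffolds without a peak beyond the first 10 kb. The 12 adult-leg-only regions had mean folds of 14.5 to 19.7, led by phaw_50.149111 at 48 to 374 (19.7 ± 3.47), phaw_50.283562c at 490570 to 490863 (17.9 ± 3.20) and phaw_50.283821 at 4023321 to 4023621 (18.7 ± 6.64; SD, n = 3 each). Of them 4 were called in a whole embryo and 3 lay on such short scaffolds. The 6 regions leading those of all 9 nuclei libraries had mean folds of 26.9 to 37.2; the first were phaw_50.283873a at 3518784 to 3519121, phaw_50.283829a at 2482078 to 2482411 and phaw_50.128425 at 1 to 416.

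Windows of 100 kb were ranked by the number of restricted regions they held. The window with the most embryonic-leg-only regions, at 25.4 to 25.5 Mb of phaw_50.282695a, held 13 of them and neither an adult-leg-only nor a leg-wide region, and 10 of the 13 were also called at stage 24. Windows at 7.5 to 7.6 Mb of phaw_50.000135e and at 5.4 to 5.5 Mb of phaw_50.282976a held 11 embryonic-leg-only regions and 1 adult-leg-only region each, and a window at 22.1 to 22.2 Mb of phaw_50.283468a tied with them at 11 and held no adult-leg-only region. Adult-leg-only regions were most frequent at 17.9 to 18 Mb of phaw_50.283850a (7, of which 2 were called at stage 24), at 12.3 to 12.4 Mb of phaw_50.283868b (6, beside 2 embryonic-leg-only regions) and at 24.9 to 25 Mb of phaw_50.283829a (5). Regions that overlap naked DNA were not left out of this ranking. On phaw_50.283850a, the adult-leg-only regions at 17953997 to 17954453 and at 17962158 to 17962839 overlapped a naked DNA peak. No embryonic-leg-only region of the window on phaw_50.282695a did. Of 47206 windows with a region, 238 held 5 or more embryonic-leg-only regions and 3 held 5 or more adult-leg-only regions.

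**Figure D4:**
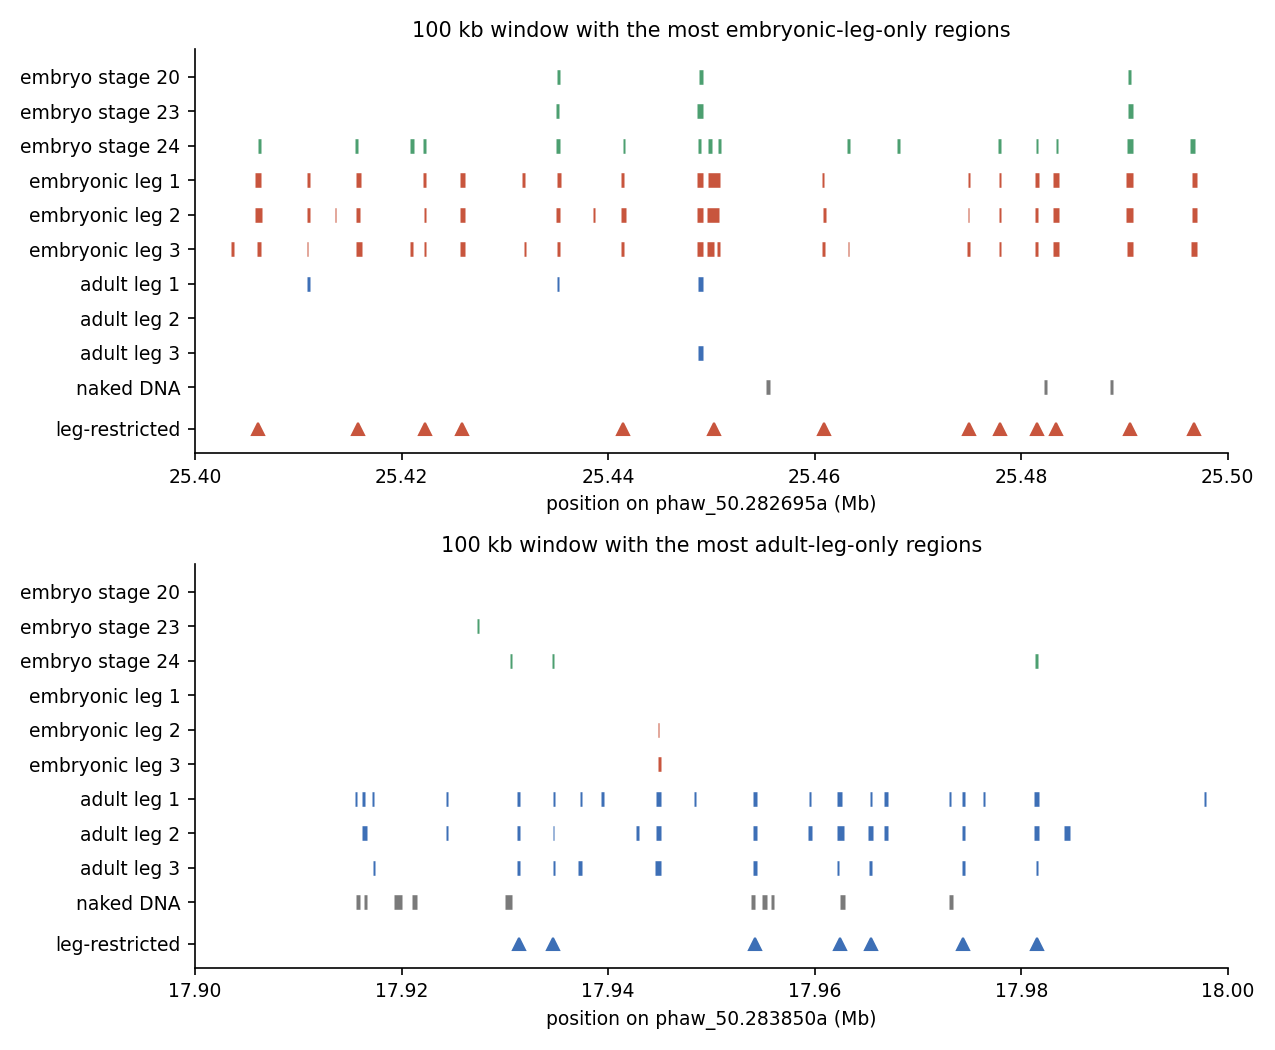
Called peaks of the 10 libraries (rows) along the 100 kb windows with the most embryonic-leg-only regions (top) and the most adult-leg-only regions (bottom); the horizontal axis is the position in Mb and triangles mark leg-restricted regions. The upper window holds 13 embryonic-leg-only regions and the lower window 7 adult-leg-only regions.

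The whole embryos did not decide the class of a region, although their peaks shaped the merged regions. They were then used to ask which leg regions were also called in embryos of earlier stages. A whole embryo holds other tissues besides its legs, so a peak there does not show that the region was accessible in legs. Embryonic-leg-only regions were found in at least 1 embryo in 73.1% of cases (95% Wilson interval 72.3% to 73.9%) and adult-leg-only regions in 25.8% (23.8% to 28.0%). On scaffolds of at least 1 Mb the shares were 73.4% and 21.3%, against 4.24% and 4.25% after random shifts there. At stages 20, 23 and 24 the embryonic-leg-only share was 23.0%, 21.3% and 67.9%, and the adult-leg-only share 11.04%, 11.9% and 14.4%. With the same number of peaks in every library these shares were 24.9%, 25.6% and 56.7% against 19.4%, 20.2% and 8.70%, and the odds ratios at the 3 stages were 1.38, 1.36 and 13.7, against 2.41, 2.01 and 12.6 as deposited. Trimming also changed the classes, to 7022 embryonic-leg-only and 2872 adult-leg-only regions, so these values do not follow the same regions. Leg-wide regions were found at 63.7%, 70.4% and 83.0%. The odds ratio of embryonic-leg-only against adult-leg-only regions was 7.80 (95% interval 6.95 to 8.76; Fisher's exact test, two-sided, p = 9.69e-311 over regions, which are not independent replicates). It was 2.52 (2.22 to 2.88) without the stage 24 embryo, 4.36 (3.98 to 4.79) with the same number of peaks in every library, 14.3 with a mean fold of at least 6, and 4.33, 4.63 and 4.18 without embryonic leg 1, 2 and 3. With regions merged from the leg libraries alone it was 7.94 (7.07 to 8.91). Leaving out stage 24, the fold minimum and the leg-only merging were chosen after seeing the data.

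**Figure D5:**
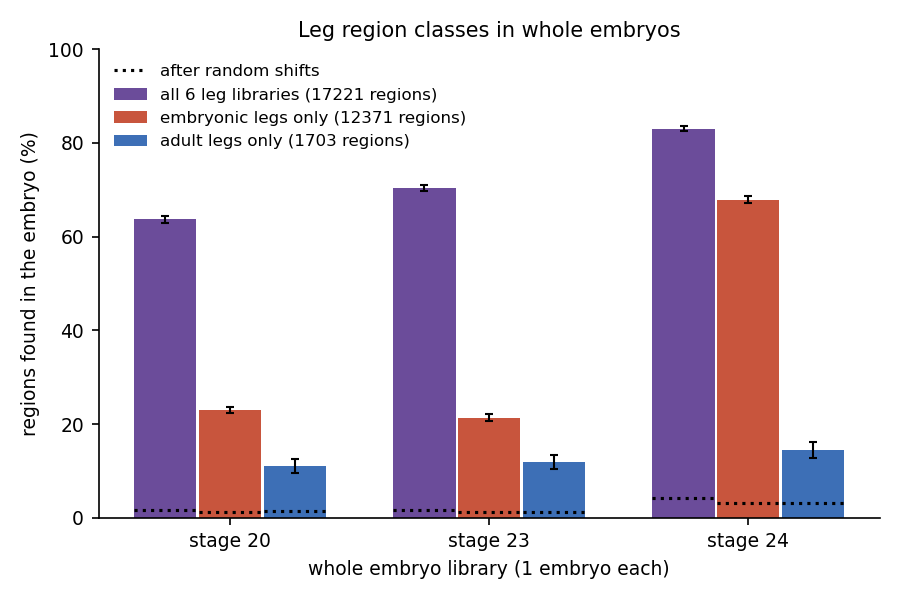
Percent of leg-wide, embryonic-leg-only and adult-leg-only regions (vertical axis) called in the whole embryo at each stage (horizontal axis, 1 embryo each), with 95% Wilson intervals and dotted lines for the mean after random shifts on scaffolds of at least 1 Mb. The embryonic-leg-only share is 23.0% at stage 20, 21.3% at stage 23 and 67.9% at stage 24.

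Among the embryos, 122923 regions were called at 1 stage, 30612 at 2 stages and 16485 at all 3. Of the regions called at all 3 stages, 96.3% were called in a leg library and 50.3% in all 6, whereas of the regions of 1 stage 40.9% were called in a leg library and 2.44% in all 6. Stage 24 had a Jaccard index of 0.265 ± 0.0169 with embryonic legs and 0.165 ± 0.0324 with adult legs (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). For stage 20 the values were 0.197 ± 0.00940 and 0.188 ± 0.0158 (exact p = 0.5, n = 3 each), and for stage 23 they were 0.207 ± 0.0144 and 0.207 ± 0.00617 (exact p = 1, n = 3 each). With the same number of peaks in every library the stage 23 values were 0.239 and 0.221 (exact two-sided p = 0.1, n = 3 each, the smallest possible). These tests of single embryos were not among those fixed beforehand. The number of regions common to the 3 stages depended on the threshold and on naked DNA, with 6547 at a q-value of at most 1e-05 and 10339 without peaks that overlap naked DNA. With 1 embryo per stage, differences between stages have no replicate check, and the stage 24 list differs from the others in its narrowest peak width (200 bp). Fewer peaks had a q-value of at most 1e-05 at stages 20 and 23 (27.0% and 27.4%) than at stage 24 (62.7%).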

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

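The odds without the stage 24 embryo and the test on groups ranked by fold within each class were chosen only after the result was seen, and the tests between stages were not among those fixed before the data were examined. The difference between embryonic-leg-only and adult-leg-only regions was not alike at the 3 embryonic stages, which is why it is singled out here. Among regions called at only one of the stages 20 and 24, the odds of being called at stage 24 were 11.47 times as high for embryonic-leg-only as for adult-leg-only regions (95% interval 8.86 to 14.9; Fisher's exact test, two-sided, p = 3.62e-62). With the same number of peaks in every library the odds ratio was 28.4 (22.6 to 35.8), and without peaks that overlap naked DNA it was 6.44 (4.50 to 9.20). For stage 23 against stage 20 it was 0.765 (0.577 to 1.01), with 0.561 (0.386 to 0.817) without naked DNA, 0.949 (0.773 to 1.17) with the same number of peaks and 0.939 (0.513 to 1.72) at a q-value of at most 1e-05. For stage 24 against stage 23 it was 12.05 (9.36 to 15.5). Each stage is 1 embryo, and the test compares these libraries.

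The higher share of embryonic-leg-only regions found in whole embryos was weighed against technical explanations. A difference in peak strength between the classes is argued against, because within 10 strata of mean fold the odds ratio was 7.19 with a lower 95% bound of 6.40, and since folds of the leg types are not on the same scale, 10 groups ranked by fold within each class were compared as well: 54.8% to 90.5% of embryonic-leg-only regions were found in an embryo against 14.7% to 38.0% of adult-leg-only regions. Bias shared with naked DNA is argued against as well, because among regions without a naked DNA peak the odds ratio was 11.5 with a lower bound of 9.98. The stage 24 library itself stays open: its narrowest peak, exactly 200 bp, differs from the other nuclei libraries and its list is the longest of the embryos. Of its peaks 62.7% had a q-value of at most 1e-05, against 27.0% and 27.4% at stages 20 and 23 and 46.6% to 63.2% in leg libraries. Weak detection at stages 20 and 23 therefore stays open as well. Without stage 24 the odds ratio was 2.52. With the same number of peaks in every library, the odds ratios at stages 20, 23 and 24 were 1.38, 1.36 and 13.7, against 2.41, 2.01 and 12.6 as deposited. The stage 24 value thus did not fall with a shorter list, although trimming also changed which regions the classes held. Lower agreement or lower sensitivity of the adult leg libraries also stays open. Either could place regions accessible in both leg types among the embryonic-leg-only regions. The age of the embryo is an untested biological explanation, and single embryos cannot separate it from a difference between libraries.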

How the results depend on the processing

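Chosen only after the results were seen were the settings that leave out the stage 24 embryo, trim its list, require a mean fold of at least 6, merge regions from the leg libraries alone, or take the same number of peaks after leaving out naked DNA. For the comparisons of the report, the ratio of the restricted counts and the odds of stage 24 against stage 20, 82 values kept their direction and size or side of the threshold, 22 moved and none reversed. The odds ratios were judged only by direction and by a Fisher's exact p under 0.05. Over so many regions that rule could hardly fail, so their kept values say little about size. For presence in whole embryos, 2.52 and 14.3 counted as kept against 7.80 as deposited. For stage 24 against stage 20, 28.4 counted as kept against 11.47. The replicate block leaves the difference in naked DNA share unchanged by construction. Similarity within against between tissues was also judged by direction and an exact permutation p under 0.05, not by size. Its difference ran from 0.0503 to 0.116 over the settings, against 0.0786 as deposited. This similarity, the ratio of peaks and the share in naked DNA were among the results counted as kept. Outside these, the adult-leg-only share rose from 11.04% at stage 20 to 14.4% at stage 24 as deposited and fell from 19.4% to 8.70% with the same number of peaks. The adult-leg-only class itself then held 2872 regions in place of 1703. The stage 23 difference in Jaccard index between embryonic and adult legs went from −0.000198 to 0.0177. The cause of these changes was not tested. Similarity within against between legs kept its direction, but the difference of 0.101 became 0.145 at a q-value of at most 1e-05, 0.131 with the same number of peaks, and 0.0686 to 0.156 when each leg library was left out in turn; the cause was not tested. Embryonic-leg-only regions numbered 7022 and adult-leg-only regions 2872 with the same number of peaks in every library, where fewer embryonic leg peaks enter by construction. A mean fold of at least 6 gave 7481 and 1012, and the same number of peaks after leaving out naked DNA (33941 per library) gave 5298 embryonic-leg-only regions, with a ratio of 2.30 between the classes. A q-value of at most 1e-05 gave 1079 adult-leg-only regions and 6547 regions common to the 3 embryo stages, and leaving out naked DNA gave 10339 of the latter; fewer peaks enter under both. Leaving out each leg library in turn gave 13174 to 21381 embryonic-leg-only and 2016 to 3631 adult-leg-only regions, since fewer libraries must then hold or lack a region. The odds ratio of stage 23 against stage 20 was 0.765 as deposited and 0.561 to 0.949 over the settings; the cause was not tested. Regions merged from the leg libraries alone gave an odds ratio of 7.94 for presence in whole embryos.

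The correlations below gave no sign that the replicate numbers pair the samples, but with 3 libraries per type they cannot exclude a weak pairing. Correlations of same-numbered embryonic and adult leg libraries, as deviations from their group means over regions, were −0.00959, −0.0349 and 0.0217, and not every library correlated best with its own number. With the replicate number as a block the ratio of peaks was 1.64 and the difference in naked DNA share −7.92 percentage points, each with an exact sign-flip p of 0.25, the smallest that 3 pairs allow (two-sided). Depth differed between libraries (0.252 for the shallowest leg library), and its effect on weak regions was not tested.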

Other observations

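The tests on the 2000 strongest regions and on pairs with a leg-wide region between them were chosen only after the results were seen; the tests of agreement, broad elements and naked DNA neighbours were set after the counts of regions but before their own values. Regions called at stages 20 and 23 and not at stage 24 numbered 4475, and 61.0% of them overlapped a naked DNA peak. The regions of stages 20 and 24 only (13050) overlapped naked DNA in 22.0% of cases and those of stages 23 and 24 only (13087) in 17.2%. Regions of stages 23 and 24 were called in all 3 embryonic leg libraries in 47.5% of cases and in all 3 adult leg libraries in 20.97%. There were 615 regions called in all 3 embryos and in no leg library, and 1171 called in all 6 leg libraries and in no embryo.

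The larger number of restricted regions in embryonic legs was weighed first. An unequal number of called peaks is argued against as the whole cause, because with the same number of peaks in every library the ratio was still 2.44, and 1.50 without adult leg 2, although it had been 7.26 as deposited. Lower agreement among adult leg libraries cannot be told apart from a real difference: the ratio of restricted shares was 1.56 at the same number of peaks and 1.29 without adult leg 2, above the bound set beforehand, but that bound overlooked that poor agreement also raises absence from all 3 adult libraries, and the within-type Jaccard index was 0.347 for adult and 0.542 for embryonic legs. Lower sensitivity of the adult libraries stays open as well, since among the 2000 strongest regions of each type 1.60% (32 regions) of the embryonic and 0.25% (5 regions) of the adult ones were missing from the other type, which covers few of the 12371 regions. Of the 10 splits of the 6 leg libraries, 1, the real one, gave 14074 restricted regions and the highest other gave 2154; 10 splits are too few for a share under 0.05, and age and leg identity remain untested biological explanations.

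Restricted regions of one class lay next to each other along scaffolds: of 13258 neighbouring pairs, 83.0% were of the same class, against a mean of 78.7% and a maximum of 79.2% in 100 random orders, which argues against chance order. One broad element called as several peaks is argued against, because 82.4% of pairs at least 10 kb apart were of the same class (random maximum 79.3%), and so is bias shared with naked DNA, with 83.9% without naked DNA regions (random maximum 81.5%). A large deletion in the animals of one group stays open: 55 of 76 adult stretches of at least 3 regions (72.4%) held a leg-wide region, past the bound set beforehand, but that bound overlooked that a long stretch holds one even where part of it is deleted. Of 5743 pairs with a leg-wide region between them, which no single deletion can span, 77.8% were of the same class, within the random orders (maximum 79.99%) but above all shuffles of their own members (maximum 76.5%), as these pairs held more adult-leg-only regions (14.1% against 9.39% in other pairs), so this test does not decide either. Shared timing of use in neighbouring elements was not tested.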
